A study of Homo sapiens with 2 samples.

How the data were processed

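Total RNA of 1 culture of LNCaP prostate cancer cells with a lentiviral miR-616 vector and 1 culture with the empty lentiviral vector was labelled with biotin and hybridized to Affymetrix 3′ arrays by a microarray service, per the labels' protocols. The probe set names are those of the HG-U133 Plus 2.0 array. The deposited values are log2 expression summaries, 1 per probe set and array, made with RMA per the submitters' processing notes. RMA corrects background, equalizes the probe distributions of arrays normalized together and summarizes the probes of a set. The software, its version and whether other arrays were normalized together are not given in the sources used here. The log2 scale was read from the values, which ran from 2.50 to 14.67 on the empty vector array and from 2.51 to 14.77 on the miR-616 array. The sorted values of the arrays differed by at most 0.22. Low values fell on few levels. The 54675 probe sets took 3254 and 3365 distinct values, and up to 897 and 872 probe sets had the same value, so differences of dim genes come in steps.

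Probe sets were named from the annotation of the array platform. Of the 54675 probe sets, 41091 had 1 gene, 1801 several genes and 11721 no name here, and 62 were controls. The gene identifiers of 41037 of the 1-gene probe sets were in the RefSeq table, which changed 0 symbols. Each gene was represented by its probe set with the highest mean of both arrays among probe sets with 1 gene. A gene was above the floor if its higher value reached the median of the means of all probe sets (log2 4.60). The difference was the miR-616 value minus the empty vector value. With 1 array per group no test across arrays can be made. Genes were counted at a fixed size of at least 2-fold, and list members at least 1.5-fold. The results describe these 2 arrays.

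The 31 gene lists, the rule for named genes and the alternatives were fixed before the data were examined. The rule named the 12 genes with the largest positive and the 12 with the largest negative difference above the floor whose other probe sets above the floor differed the same way. It left out sex-linked markers and clone, LOC, open reading frame and LINC symbols. It added 10 fixed genes, of which 7 had a probe set named here and the others were not analysed here, and up to 4 members of each list with the largest absolute difference. Other members of a list are given as examples. A list's median over members above the floor was set against 10000 random lists of the same size, drawn from 20 bins of mean expression with the members left out. A list was outside the range of random lists if its median lay outside the central 95% of the random medians.

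The alternatives were removal of the loess trend of the difference on brightness (fraction 0.3), removal of the median difference, the mean of all probe sets of a gene, leaving out probe sets whose names end in _s_at, _x_at or _a_at, no floor, a floor at percentile 70 (log2 6.35), a threshold of 1.5-fold, log2 of the linear value plus 32, and random lists without matching. Random lists matched on expression, gene length and the number of coding genes within 500 kb were added after seeing the data. Sites of miR-616 in 3′ untranslated regions were not analysed here, because they need transcript sequences. The steps were tested on simulated data, with the spread taken from these arrays, for the comparison of miR-616 with empty vector over 13464 genes. At the 2-fold limit, 43% of 100 genes changed 2-fold and 99% of 100 genes changed 4-fold were recovered, and 2.40% of 13264 unchanged genes passed it, a share that this spread sets and that is no benchmark for the observed count. Of 200 lists of 30 unchanged genes 2.5% fell outside the range, and 100% of 200 lists raised by 0.3 were above it. The simulated noise was independent between genes, so these shares do not cover lists of genes that vary together. Shifts of lists smaller than 0.3 were not simulated. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.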

Results

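Gene expression was measured on 2 Affymetrix arrays, 1 of LNCaP cells stably carrying a lentivirus that overexpresses the microRNA miR-616 and 1 of LNCaP cells carrying the same kind of vector without the microRNA. LNCaP is an androgen-sensitive human prostate cancer cell line. Each group was 1 array, so no difference has a replicate check, and no p-value, standard error or standard deviation between replicates is given. The precision is limited by this number of arrays. The table held 54675 probe sets, which gave values for 19775 genes. Of these, 13464 genes reached the expression floor, a log2 value of 4.60 on at least 1 array. The arrays had median log2 values of 4.57 (empty vector) and 4.65 (miR-616), and their values correlated across probe sets with r = 0.985 (Spearman's rho = 0.963). Probe sets are not independent replicates. All differences below are miR-616 minus empty vector on the log2 scale.

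The comparison asks which transcripts differ between LNCaP cells with and without added miR-616. Work on miR-616 in these cells has studied TFPI2, a secreted inhibitor of serine proteases that include the tissue factor and factor VIIa complex. TFPI2 was dim on both arrays. The brighter of its probe sets had log2 values of 5.13 with the empty vector and 4.29 with miR-616, a difference of -0.84, or 1.79-fold lower with miR-616, so that it passed the floor with the empty vector alone. The other TFPI2 probe set was below the floor on both arrays (3.28 and 3.13). With the mean of both probe sets the difference was -0.50. F3, which encodes tissue factor, had 1 probe set, with 3.54 and 4.82 (difference 1.29), so that it passed the floor on the miR-616 array alone. DDIT3, the stress-induced transcription factor CHOP whose gene carries MIR616 in an intron, had 8.81 and 10.04 on its single probe set, 2.34-fold higher with miR-616. A probe set of DDIT3 mRNA does not check the vector, and the level of miR-616 itself was not analysed here.

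The largest difference was that of HINT3, a member of the histidine triad family of nucleotide hydrolases. Its brightest probe set had a log2 value of 8.11 with the empty vector and 10.90 with miR-616, 6.94-fold higher. The other HINT3 probe sets were also higher, by 2.52 and 0.74. The largest negative difference of a bright gene was that of TXNIP, the thioredoxin-interacting protein that restrains glucose uptake. TXNIP had 10.54 with the empty vector and 8.88 with miR-616, 3.17-fold lower, and its other probe sets differed by -1.11 and -0.72. Among the 7973 genes with a mean log2 value of 7 or more, 9 were at least 2-fold higher with miR-616 and 1, TXNIP, at least 2-fold lower. Besides HINT3 and DDIT3, the 9 were POLK, a translesion DNA polymerase (2.53-fold), MOB1B, an activator of the LATS kinases of the Hippo pathway (2.41-fold), ZNF292 (2.19-fold), KRR1, a factor of small ribosomal subunit assembly (2.16-fold), the nuclear pore gene POM121C (2.07-fold), the receptor phosphatase PTPRS (2.05-fold) and ZNF91 (2.05-fold). Second probe sets differed by less for POLK (0.39), ZNF292 (0.32) and ZNF91 (0.03), that of PTPRS differed by -0.22, and those of KRR1 differed by 0.18 to 1.06. MOB1B and POM121C had 1 probe set above the floor each, so no other probe set checks them. This limit on brightness was chosen after the values were seen.

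**Figure D1:**
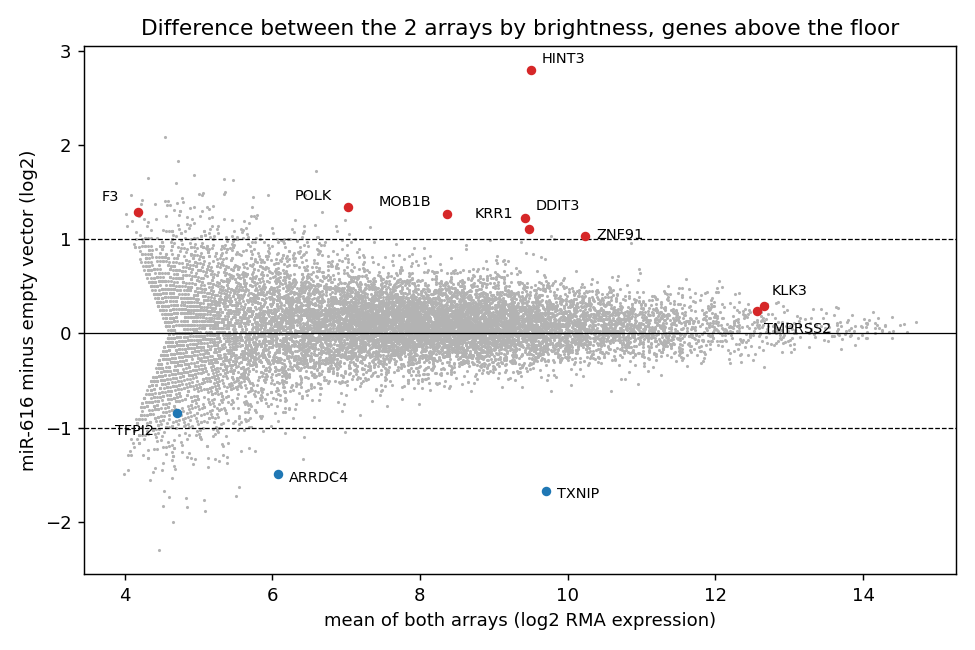
Difference between the arrays (miR-616 minus empty vector, log2, vertical axis) against the mean of both (log2, horizontal axis), 1 point for each of the 13464 genes above the floor; dashed lines mark 2-fold. HINT3, DDIT3 and TXNIP lie outside the lines among bright genes, while most points outside them are dim genes with a mean under 6.

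The other genes named by the fixed rule were mostly dim. After HINT3, the genes with the largest positive differences were PRB3 (1.83), PTPN20 (1.72), TAS1R1 (1.65), SPDYE2 (1.64), ANKRD50 (1.63), ZDHHC1 (1.60), FRMD1 (2.82-fold higher), AMOTL1 (1.49), NUS1P3 (1.48), PTGR2 (1.48) and LRRTM4 (1.47). AMOTL1 encodes an angiomotin-like protein that binds YAP, and PTGR2 a prostaglandin reductase. The genes with the largest negative differences were the olfactory receptor OR51B2 (-2.30), ITM2A (3.99-fold lower), the acrosomal protease ACR (-1.88), FEZ1 (-1.84), SLAMF9 (-1.83), RYR3-DT (-1.76), LCNL1 (-1.74), the estrogen receptor beta gene ESR2 (-1.73), PPP1R18 (-1.73), KLF3-AS1 (-1.68), TXNIP and the T cell antigen CD5 (-1.62). Of the 12 higher genes 11 had 1 probe set above the floor, and 9 had a mean under 6. Of the 12 lower genes 9 had 1 probe set above the floor, and 11 had a mean under 6. Of the higher genes 6 lay below the floor with the empty vector, and of the lower genes 9 lay below it with miR-616, among them OR51B2, ITM2A, ACR and FEZ1, so the sizes and the order of these differences are not firm. With the mean of all probe sets of a gene, 1 of the 5 higher genes and 3 of the 8 lower genes that have several probe sets stayed at 2-fold. The mean was 0.31 for AMOTL1, 0.56 for ANKRD50, 0.78 for TAS1R1, 0.98 for ZDHHC1, -0.34 for ESR2, -0.65 for FEZ1, -0.87 for SLAMF9, -0.96 for ITM2A and -0.98 for KLF3-AS1.

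In all, 153 genes were at least 2-fold higher and 126 at least 2-fold lower with miR-616, together 2.07% of the genes above the floor. With 1 array per group there is no count expected without a difference to set beside it. Of the counted genes 54.8% were higher. This split depends on the scaling between the arrays. With the median difference of all probe sets subtracted it was 107 higher and 166 lower (39.2% higher), and with the loess trend on brightness removed it was 75 higher and 209 lower (26.4% higher). The loess step moved the median difference of genes above the floor by -0.13, from 0.08 to -0.05. Of the 3570 genes with a mean under 6, 123 were 2-fold higher and 119 lower. Of the 3944 genes with a mean from 8 to 10, 5 were higher and 1 lower. Probe sets of the same gene gave the available measure of precision within these arrays. Across 6286 genes with at least 2 probe sets above the floor, the median SD of the difference between probe sets of a gene was 0.28. Of 48 genes at 2-fold with another probe set, 33 had their next probe set in the same direction, and 11 had it at 1.5-fold or more.

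The control probe sets differed between the arrays by their position along the transcript. For the poly-A spike-ins, added to the RNA before labelling, the median difference was 1.36 at the 5′ end, 1.12 in the middle and 0.50 at the 3′ end. For ACTB it was 0.47 at the 5′ end and 0.14 at the 3′ end, and for GAPDH 0.43 and 0.07. The hybridization spike-ins, added after labelling, had medians of 0.27 and 0.25. The ribosomal RNA controls went the other way, with medians of -0.08 at the 5′ end, -0.73 in the middle and -0.47 at the 3′ end (2 probe sets each). Within a gene, the dimmer probe sets were higher with miR-616 than the brightest one by a median of 0.14, in 63.2% of the 6286 genes. The difference was also larger for long genes and for genes in gene-poor regions. Its median went from 0.01 in the shortest to 0.13 in the longest quintile of 12296 genes, and from 0.14 in the most gene-poor to 0.02 in the most gene-dense quintile.

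**Figure D2:**
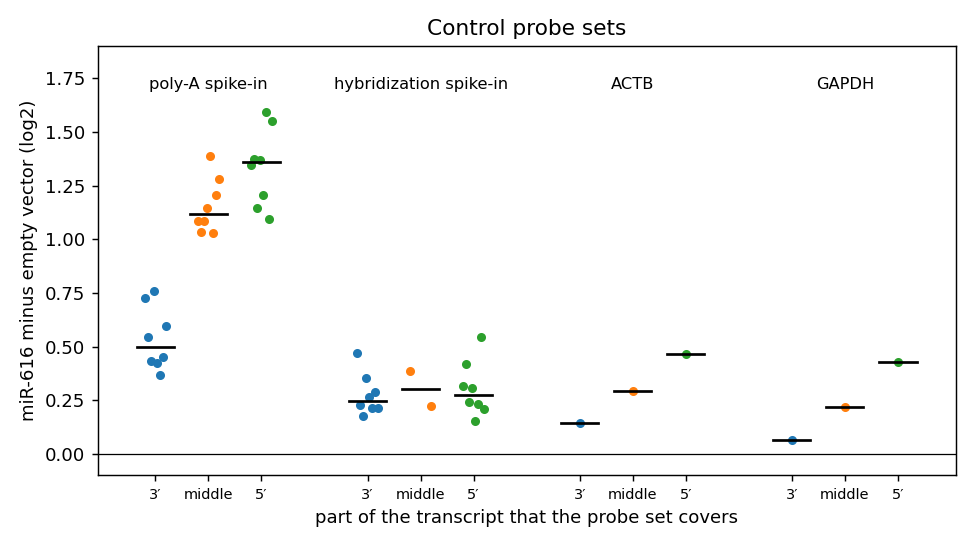
Difference between the arrays (miR-616 minus empty vector, log2, vertical axis) of control probe sets by the part of the transcript they cover (horizontal axis); points are probe sets and bars their medians. The poly-A spike-ins go from a median of 0.50 at the 3′ end to 1.36 at the 5′ end, and the hybridization spike-ins stay near 0.25.

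Genes of the unfolded protein and integrated stress response were higher with miR-616 as a group. Of 38 members, 34 had a difference above 0, 8 were at least 1.5-fold higher and 0 at least 1.5-fold lower. The largest differences were those of the lipoprotein receptor gene VLDLR (1.25), DDIT3 (1.23), the endoplasmic reticulum chaperone HSP90B1 (1.00) and the glutathione-degrading enzyme CHAC1 (0.88). XBP1, the transcription factor of the IRE1 branch, differed by 0.78, TRIB3, a target of ATF4, by 0.77, and ATF4 itself by 0.30. The chaperone gene CALR had a difference of -0.19, and PPP1R15A, a phosphatase subunit that reverses the translation block, -0.22. The 13 chaperones and folding enzymes of the endoplasmic reticulum had a median of 0.10, inside the range of random lists (percentile 69.9). This subset was chosen after the values were seen. The median of the list was 0.37, at percentile 100 of 10000 random lists of the same size and expression, whose medians ran from -0.01 to 0.16 in their central 95%. The heat shock and chaperone genes were higher too, with a median of 0.24 over 19 genes (percentile 99.6). In that list 4 genes were at least 1.5-fold higher, DNAJB6 (0.72, just below the floor with the empty vector), HSPA4L (0.72), DNAJB4 (0.69) and the heat shock transcription factor HSF1 (0.64), and 0 were 1.5-fold lower. Other members were flat or lower, among them HSP90AA1 (0.01), HSPD1 (-0.01), HSPH1 (-0.03), HSPA4 (-0.28) and SERPINH1 (-0.44). Other probe sets of HSPA4 differed by 0.20 to 0.59 and that of HSPH1 by 0.48. Between the same arrays the difference of the 5′ control probe sets exceeded that of the 3′ ones. The excess was 0.86 for the poly-A spike-ins, 0.32 for ACTB and 0.36 for GAPDH. Whether it bears on the heat shock list was not tested.

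Genes of DNA replication and of mitosis were slightly lower with miR-616, relative to genes of like expression, when each gene was read from its brightest probe set, with 0 members of either list at 1.5-fold. The S phase list had a median of -0.09 over 40 genes, at percentile 0 of the matched lists, and 22 of its genes had a difference below 0. The primase and polymerase alpha subunit POLA2 differed by -0.49, the flap endonuclease FEN1 by -0.49 and the replicative helicase subunit MCM5 by -0.32, while the primase subunit PRIM2 differed by 0.44. A second probe set of FEN1 differed by 0.25, and those of POLA2 by -0.24 and 0.19. The mitotic list had a median of -0.07 over 38 genes (percentile 0.01). CDC20, the activator of the anaphase-promoting complex, differed by -0.33, and AURKB (0.53, with another probe set at -0.26), the centromere histone CENPA (0.52) and KIF23 (0.48) differed the other way. The uneven 5′ signal of the control probe sets may bear on these genes as well. With the mean of all probe sets of a gene both medians were above 0, 0.02 for S phase (percentile 1.86) and 0.04 for mitosis (percentile 6.32, inside the range), against 0.11 for matched lists. Without probe sets that can match several transcripts the mitotic median was 0.01 (percentile 10.97). The matched random lists of both had a median of 0.08. Cyclins and CDK inhibitors of G1 lay within the range of random lists (median 0.09 over 21 genes, percentile 54.3), with CDKN1C (0.66, others -0.43 to 0.11) and RBL2 (0.63) at 1.5-fold.

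Androgen-induced genes were slightly higher with miR-616, relative to genes of like expression. KLK3, which encodes prostate-specific antigen, had log2 values of 12.52 and 12.81 (difference 0.29, other probe sets 0.28 and 0.58). TMPRSS2 had 12.44 and 12.68 (difference 0.24, other probe sets 0.38 to 0.73). The hybridization spike-ins, added after labelling, differed by about as much, with medians of 0.27 at the 5′ end and 0.25 at the 3′ end. For KLK2 the difference was 0.06, with a range of -1.32 to 0.63 in its other probe sets, and for the FK506-binding protein gene FKBP5 it was 0.09, with its other probe sets at 0.62 and 0.83 and the mean of all at 0.51. KLK2 was at -0.03 with the loess trend removed and at -0.13 with the mean of all probe sets. Over 32 androgen-induced genes the median was 0.17 (percentile 98.9) and 26 were above 0. TRPM8 (0.66) and KLK4 (0.61) were at least 1.5-fold higher and 0 genes 1.5-fold lower. Without a floor the median was also 0.17, against 0.07 for matched lists, and with the loess trend removed it was 0.08, against -0.03. A second probe set of TRPM8 differed by -0.38, and those of KLK4 by -0.50 to 0.82. Androgen-repressed genes above the floor were also higher, with a median of 0.37 over 9 genes (percentile 99.5) and GRIN3A (0.89) at 1.5-fold, though GRIN3A was below the floor with the empty vector (4.06), so its size is not firm. BCHE differed by 0.43 and DDC by -0.44. Without probe sets that can match several transcripts these percentiles were 93.2 and 93.9, inside the range of random lists. Induced genes also came inside it at 94.11 without matching and at 96.78 with gene length and density matched, a comparison added after seeing the data. Repressed genes came inside it at 84.14 without a floor, where the median of 14 genes was 0.11. They did so too at 96.44 with the mean of all probe sets and at 97.29 with the higher floor. Whether the larger difference of the 5′ control probe sets bears on these lists was not tested. Genes of androgen synthesis and inactivation had a median of -0.04 over 14 genes (percentile 12.04), with the steroid sulfatase STS (-0.67) and AKR1C1 (-0.61, others -0.46 to 0.34) at least 1.5-fold lower.

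**Figure D3:**
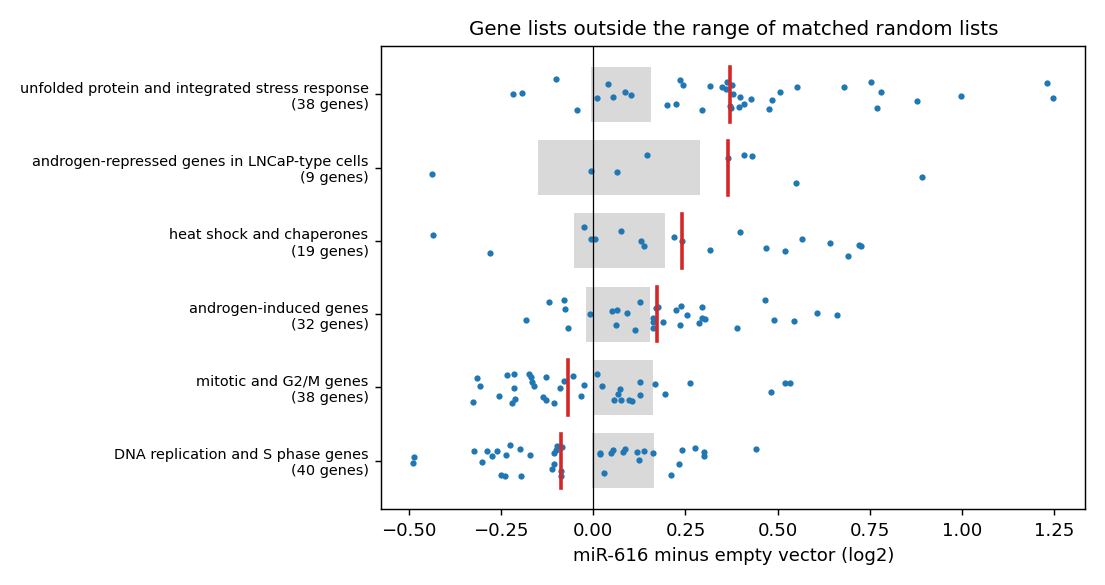
Differences of the members of the 6 gene lists outside the range of matched random lists (miR-616 minus empty vector, log2, horizontal axis); points are genes, red bars the list medians and grey boxes the central 95% of random medians. The stress response list has its median at 0.37, above its box, and the S phase list at -0.09, below its box.

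Markers of prostate and other cell types lay within the range of random lists in the main setting, though 4 of these lists left it in others. Luminal epithelium markers had a median of 0.20 over 15 genes (percentile 96.2), with MUC1 at 0.77 and the E-cadherin gene CDH1 at 0.44. Basal markers had 0.11 over 5 genes (percentile 57.5), with S100A2 at 0.99. Neuroendocrine markers had -0.11 over 8 genes (percentile 18.5), but percentile 1.99 with the mean of all probe sets and 0.77 without a floor. SCGN differed by 0.77 (below the floor with the empty vector), while the brightest members, TUBB3 and DDC, differed by -0.23 and -0.44. Fibroblast and stromal markers had -0.17 over 11 genes (percentile 10.1), with the collagen gene COL6A3 (-1.14) and SPARC (-0.78) at least 1.5-fold lower. Endothelial and leukocyte markers had -0.19 over 6 genes (percentile 24.4), with CSF1R at 0.93 and CD3D at -0.91. Mesenchymal markers and markers of androgen-insensitive prostate lines had 0.03 over 12 genes (percentile 43.1), but without probe sets that can match several transcripts 5 genes were left, with a median of -0.58 (percentile 0.23). In this list 3 genes were 1.5-fold higher and 3 lower. They included SNAI1, a repressor of epithelial genes (-1.17), the galectin gene LGALS1 (-0.90), the N-cadherin gene CDH2 (0.67) and the receptor gene EGFR (0.65), whose other probe sets differed by -1.40 to 0.76. Most of the members named here were dim, and many lay below the floor on 1 of the arrays.

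The tissue factor pathway and pericellular proteolysis genes went both ways. The median was 0.06 over 19 genes (percentile 56.0), with 4 genes at least 1.5-fold higher and 2 lower. F3 (1.29), the protein C receptor gene PROCR (0.93) and S100A10 (0.91), a binding partner of annexin A2, were higher, and the tissue plasminogen activator gene PLAT (-1.29) and TFPI2 (-0.84) were lower. Each of these 5 genes lay below the floor on 1 array, so the sizes are not firm. Matrix metalloproteinases and their inhibitors had a median of 0.01 over 14 genes (percentile 19.9, but 98.45 with the mean of all probe sets), with the inhibitors RECK (1.02, other probe sets 0.40 and 0.46) and TIMP2 (0.67) higher and TIMP1 (-0.70) lower. Cell adhesion molecules had 0.16 over 30 genes (percentile 96.1, but 99.01 with the mean of all probe sets and 50.96 without probe sets that can match several transcripts), with the desmosome gene PKP2 at 1.09 (below the floor with the empty vector) and the integrin gene ITGB3 at -0.70, whose other probe sets above the floor went the other way (0.38 and 0.67).

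Other stress and signalling lists lay within the range of random lists. Apoptosis regulators had a median of 0.03 over 27 genes (percentile 18.8), with BAX at 0.86 and CASP6 at -0.77, whose other probe set was at 0.66. Genes regulated by p53 had 0.02 over 24 genes (percentile 18.9), with GADD45A at 0.77 and ZMAT3 at 0.82, whose other probe sets ranged from 0.01 to 1.14. Type I interferon response genes had 0.04 over 29 genes (percentile 29.2), with IFIT3 at -1.29 and OAS3 at 0.70. NF-kB and inflammatory genes had 0.06 over 16 genes (percentile 47.1), with TNF at -0.89 (below the floor with miR-616). Immediate early genes had 0.12 over 28 genes (percentile 73.8), with SPRY2 at 0.83. Targets of the WNT pathway had 0.17 over 13 genes (percentile 80.9), with APCDD1 at 0.79. Among factors of microRNA processing and silencing, with a median of 0.11 over 21 genes (percentile 65.7), DICER1, which cuts microRNA precursors, was at 0.82, and its other probe sets were at 0.26 to 1.09.

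Metabolic and housekeeping lists also lay within that range in the main setting, though 3 of the 7 left it in others. Hypoxia and glycolysis genes had a median of 0.14 over 33 genes (percentile 93.8), with VEGFA at 0.48. Oxidative phosphorylation subunits had 0.01 over 40 genes (percentile 2.83, and 2.41 with the loess trend removed), with NDUFB6 at -0.34. Cholesterol synthesis and uptake genes had -0.01 over 22 genes (percentile 5.12, and 2.2 with the loess trend removed), with HMGCS1 at -0.53 and its other probe set at 0.69. Fatty acid synthesis genes had 0.08 over 19 genes (percentile 57.6), with ACSL1 at 0.55. Metallothioneins and metal response genes had -0.03 over 17 genes (percentile 5.49, and 1.12 with the mean of all probe sets), with MT1X at -0.61. Replication-dependent histones had 0.04 over 18 genes (percentile 37.7), with H4C5 at -1.12 (below the floor with miR-616). Cytosolic ribosomal proteins had 0.07 over 44 genes (percentile 67.9), with RPL8 at 0.28. Of the 31 lists, 6 lay outside the range of random lists. By chance 1.55 would, if the genes of a list varied as independently as those of random lists. That condition was not tested, and some lists share genes.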

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

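The test of a difference between the cultures and both tests on HINT3 were chosen after their results were seen, and matching on gene length and gene density was added after the data were examined. The measurements outside the gene comparison showed differences between the arrays. The 5′ probe sets of the poly-A spike-ins, RNAs added to the samples and not made by the cells, had a median difference of 1.36 (range 1.09 to 1.59), while their 3′ probe sets had 0.50. Probe sets above the floor that have no gene name here, 4014 in number, had a median difference of 0.193, against 0.130 for 25415 probe sets with a name. Of the unnamed ones 5.85% were at least 2-fold higher and 1.92% at least 2-fold lower, against 3.13% and 0.858% of the named ones.

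The higher unfolded protein and integrated stress response genes were set against the uneven 5′ signal. When each of the 22 members with at least 2 probe sets was represented by its smallest difference, their median stayed at percentile 99.99 of lists matched on expression and number of probe sets. For these 22 genes this argues against that signal as the whole cause, though the position of the probe sets was not used. VLDLR, DDIT3 and CHAC1, with 1 probe set above the floor each, were not covered. Matching on gene length and gene density left the median of all 38 members at percentile 100, which argues against that trend. A difference between the cultures other than miR-616, such as density or nutrients at harvest, may also raise these genes, and with 1 array per group it cannot be told apart from miR-616. Both miR-616 and such a difference stay open.

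The lower DNA replication and mitotic genes were tested in the same way. Matching on gene length and gene density left both lists together (78 genes) at percentile 0, which argues against that trend. With the 38 genes that have at least 2 probe sets represented by their largest difference, the median was at percentile 55.3 (0.37 against a median of 0.36 for random lists), while the same genes read from their brightest probe set were at percentile 0.22 (-0.03 against 0.08). The central range of the random medians of largest differences ran from 0.24 to 0.50. A shift as small as that of the brightest probe sets could stay inside it. Taking the largest difference also favours the most raised probe set of a gene. This test therefore cannot decide whether uneven 5′ signal between the arrays explains the pattern, and that explanation stays open. An effect of miR-616 was not excluded.

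The higher HINT3 signal was seen on 3 probe sets. A gain of the chromosome region would raise its neighbours, but the 10 nearest genes above the floor had a median difference of 0.0935 (range -0.29 to 0.51). This argues against a gain of the whole stretch that holds these genes. The highest value was that of TRMT11. A gain limited to HINT3 and a gene beside it would hardly move this median and was not tested. Signal of another transcript on 1 probe set would leave the others without a difference, but the second largest difference was 2.52. A difference of HINT3 RNA between these cultures, from miR-616 or from another source such as the site of vector insertion, remains a hypothesis that these arrays may not resolve.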

How the results depend on the processing

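Each group was 1 array, so no replicate could be left out. No paired analysis was possible because each group has a single array. Of the comparisons of gene lists with an alternative, 219 stayed on their side of the threshold, 10 came to lie outside the range of random lists, 9 came to lie inside it and 1 reversed. The cause was not tested for any of them. Removing the median difference moves all genes by the same amount and so says nothing about list percentiles. It gave 31 of the 219, which were fixed in advance. For single genes 51 values moved by less than the median SD between probe sets and 27 by more, and 3 had the other sign, all of KLK2. The 51 include 31 values with the loess trend removed, a step that moved none by more. With the mean of all probe sets 15 values moved by more and 16 by less. Genes with 1 probe set cannot move there, so the 51 are no measure of stability. The rest of the 27 values that moved by more came from other settings than these. The 153 higher genes became 75 with the loess trend removed, 93 with the mean of all probe sets, 38 with the floor at percentile 70, 892 at 1.5-fold and 9 with 32 added to linear values. The 126 lower genes became 209, 69, 11, 555 and 4. The dim genes that the higher floor and the added 32 remove or shrink hold most of these counts, so low signal over background limits them.

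Percentiles that left the range were, with the loess trend removed, 97.67 for luminal markers, 2.2 for cholesterol genes and 2.41 for oxidative phosphorylation. With the mean of all probe sets they were 1.99 for neuroendocrine markers, 1.12 for metallothioneins, 99.01 for adhesion molecules and 98.45 for metalloproteinases (reversed from 19.93), and without probe sets that can match several transcripts 0.23 for mesenchymal markers and 1.69 for cholesterol genes. Without a floor neuroendocrine markers were at 0.77, and fibroblast markers at 1.11 without matching. Percentiles that came inside were those of androgen-induced genes (93.23 without such probe sets, 94.11 without matching, 96.78 with length and density matched), androgen-repressed genes (96.44 with mean probe sets, 93.94 without such probe sets, 84.14 without a floor, 97.29 with the higher floor) and mitotic genes (6.32 and 10.97). TFPI2 was at -0.50 with mean probe sets. The stress response, heat shock and S phase lists stayed outside the range in each of these settings that gave a value. Some small lists had too few genes for a value with the higher floor, mean probe sets or fewer probe sets. The planned comparison of seed sites was not run.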

Other observations

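The subsets, families and trends below were chosen after the values were seen. TXNIP belongs to the alpha-arrestins, and the next member with a large difference was ARRDC4, at 6.82 with the empty vector and 5.33 with miR-616, 2.82-fold lower. TXNIP and ARRDC4 are both induced by glucose through the transcription factor MondoA. The other members, ARRDC1, ARRDC2 and ARRDC3, differed by -0.12, 0.16 and 0.15. Within the stress response list, the 13 chaperones and folding enzymes of the endoplasmic reticulum had a median of 0.10, inside the range of random lists (percentile 69.9), with 2 genes at least 1.5-fold higher. The remaining 25 genes, among them DDIT3, CHAC1 and TRIB3, had a median of 0.40 (percentile 100), with 6 at least 1.5-fold higher.

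Genes named ZNF followed by a number, most of which encode zinc finger proteins, were higher as a family when each was read from its brightest probe set. Of 344 genes above the floor, 232 had a difference above 0, 38 were at least 1.5-fold higher and 7 lower, and the median was 0.15 (percentile 99.95 of lists matched on expression). Matched also on gene length and gene density, the family was at percentile 100, and without probe sets that can match several transcripts it was at 99.97. The trend with length and density does not account for the whole difference in these tests. Probe sets were left out by the ends of their names alone, so signal shared between related transcripts on the remaining ones was not tested. Whether uneven 5′ signal plays a part stays open. With the 153 genes that have at least 2 probe sets represented by their smallest difference, the family was at percentile 93.65 (median -0.02 against -0.07 for random lists), but the same genes read from their brightest probe set were already at 93.5 (0.13 against 0.10). The difference across 12296 genes correlated with gene length at a Spearman's rho of 0.130 and with gene density at -0.143, across genes, which are not independent replicates.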
